A study of Homo sapiens with 9 samples.

How the data were processed

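RNA was sequenced from WI-38 cells, an established line of diploid fibroblasts from human fetal lung. Cells near population doubling level 40 received 50 nM siRNA by lipid transfection, and RNA was taken 48 hours later. The 9 libraries fall into 3 groups of 3: a pool of non-targeting siRNAs (control siRNA) and each of 2 siRNAs against PTCHD4 (siRNA 1 and siRNA 2). The labels name no treatment that induces senescence. The siRNA sequences, the annotation release and the strandedness of the libraries are not given in the sources used here.

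The deposited files, 1 for each library, hold expected counts, that is estimated read counts for 26475 gene symbols that were not scaled between libraries. The submitters' notes name Bowtie2 2.1.0, RSEM 1.2.15 and edgeR with human build hg38, and give no role for each. Fractional values occurred in 1359 to 1520 genes of a library. Counts were rounded to whole numbers, which changed the total of a library by at most 29.0 counts. These files cannot separate reads of overlapping genes or of near-identical copies; among the genes named this touches SMN2 with SMN1, HBD, CXCL1, TNXB, KRT8 with KRT18, and the ribosomal proteins. Gene coordinates were taken from GENCODE v29 on GRCh38, in which 23825 of the symbols were found once.

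Libraries held 37112523 to 48120208 estimated counts. A floor of 3 counts came to between 0.0623 and 0.0808 CPM (counts scaled to a common library total), and that floor and the binomial intervals cover counting error only. In all, 6989 symbols had no count in any library, and 14185 genes passed the filter on low counts (filterByExpr of edgeR).

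All 9 libraries were fitted together in R 4.3.3 with edgeR 4.0.16 (TMM scaling, quasi-likelihood F test, group as the only term). Each siRNA was compared with the control siRNA, and siRNA 2 with siRNA 1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, over all tested genes within a comparison. Standard errors of log2 fold changes were the absolute fold change divided by the square root of F. CPM values were scaled by TMM. The labels do not say whether the 3 replicates were separate cultures, so the p-values measure only the spread between these libraries. Tested on simulated data (14007 genes, siRNA 1 against control), the fit recovered 89% of 100 genes changed 2-fold and 59% of 100 changed 1.3-fold, with 7 false calls. Only these genes were changed with siRNA 1, in equal numbers up and down. The simulation therefore does not show how many false calls arise where most genes change, as in these data.

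The tests, the 25 gene lists and the rule for naming genes were fixed before the data were examined. Of 649 list entries, 642 were matched to the files, 11 of them through an older symbol. Each list was tested with camera (limma 3.58.1, preset correlation between genes of 0.01, adjusted over the 25 lists of a comparison), which compares a list with all other tested genes. Camera with a correlation estimated for each list and fry were run beside it. The p of fry tests whether the genes of a list move on balance one way, its mixed p tests for change in either direction, and neither compares a list with other genes. Members of a list were counted as called over all tested genes and also adjusted over the list alone.

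Genes were named by a rule with 6 parts. The first part is PTCHD4. The next takes the 10 largest rises and 10 largest falls with each siRNA, the one after it the 10 largest of each that moved the same way with both, and the fourth the 5 largest each way between the siRNAs. These needed a call, a mean log2 CPM of at least 1 and no overlap between the 3 libraries of each group; symbols starting with LOC, LINC, MIR or SNOR, antisense symbols and pseudogene copies were skipped. The fifth takes up to 4 called members of each list with the smallest adjusted p, and the last is a fixed set of genes of the cell cycle, p53, hedgehog, apoptosis and senescence. Results of some genes are not reported here.

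Both comparisons with control share the same 3 control libraries. To show what this sharing gives by itself, 20 sets of 9 libraries were simulated from the control means and the fitted dispersions, with no change in any group.

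Alternatives changed 1 choice at a time: RLE size factors, total counts only, DESeq2 1.42.0, limma-voom, no filter on low counts, a stricter filter (at least 1 CPM in 3 libraries and a mean of 10 counts), unrounded counts, only the groups compared, replicate number as a block, a 2-fold minimum, and each of the 9 libraries left out in turn. A different pseudocount was listed for normalized values only and was not run, because the files hold counts. Group labels were also exchanged in all 10 splits of the 6 libraries of each comparison, and in 100 of 840 splits of the 9 libraries.

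For the closing section, the 3′ UTR of 12506 tested genes (88.2%) was taken from GENCODE v29, 1 transcript per gene. For each of 16175 7-mers found in at least 50 of these genes, the log2 fold changes (limited to 3 either way, and adjusted for UTR length, GC content and expression) of genes with and without it were compared as a z value. Over 20 permutations the largest absolute z was 5.05. Libraries were also thinned to the smallest total for a count of genes detected. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for these steps and for the plots.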

Results

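RNA was measured in 9 libraries of WI-38 fibroblasts, 3 with control siRNA, 3 with PTCHD4 siRNA 1 and 3 with PTCHD4 siRNA 2. The series asked what PTCHD4, a gene of the patched-domain family, does in these cells by silencing it in separate ways. Control libraries held 47414275, 45604017 and 48120208 estimated counts, siRNA 1 libraries 44407739, 41906191 and 43041013, and siRNA 2 libraries 43641717, 45898588 and 37112523. The most abundant gene was COL1A1, which encodes a chain of type I collagen and took 1.27 to 2.17% of the counts of a library. Genes with any count numbered 16899 to 17163 in control libraries, 16831 to 16996 with siRNA 1 and 15853 to 16592 with siRNA 2. The first principal component held 65.7% of the variance and the second 22.8%. Levels below are means ± SD of 3 libraries in CPM (counts scaled to a common library total), and errors of log2 fold changes are standard errors (SE) from edgeR.

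PTCHD4 mRNA fell with both siRNAs, and it fell further with siRNA 2. PTCHD4 (chromosome 6, 47878028 to 48068689 on GRCh38) stood at 10.1 ± 1.04 CPM with control siRNA, 7.56 ± 0.421 CPM with siRNA 1 and 2.46 ± 0.211 CPM with siRNA 2 (n = 3 each). These levels were 75.2% of control with siRNA 1 and 24.5% with siRNA 2. The log2 fold change was −0.41 ± 0.0924 with siRNA 1 (edgeR adjusted p = 0.00218) and −2.04 ± 0.106 with siRNA 2 (edgeR adjusted p = 5.16e-09). The siRNAs differed from each other by −1.63 (edgeR adjusted p = 4.48e-08). The 3 libraries of each PTCHD4 siRNA lay below all 3 control libraries, with 427 to 559 estimated counts in controls, 295 to 341 with siRNA 1 and 98 to 105 with siRNA 2.

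**Figure D1:**
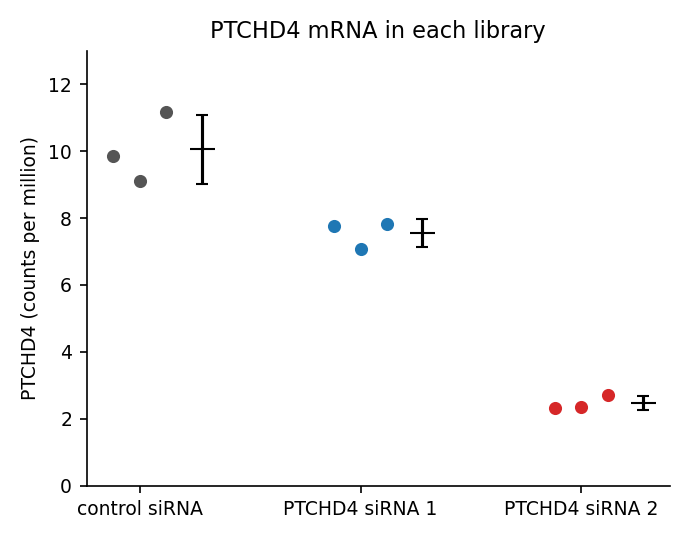
PTCHD4 level of each library in CPM by siRNA group, with the mean and SD of 3 libraries beside the points. The siRNA 2 libraries lie between 2.33 and 2.70, the siRNA 1 libraries between 7.07 and 7.83, and the control libraries between 9.12 and 11.2.

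With siRNA 1 against control, which asks what changed when PTCHD4 was lowered by this siRNA, p53 targets rose as a list (camera adjusted p = 0.00418 with an estimated correlation). Camera also called interferon-stimulated genes higher and genes of mitosis and cholesterol synthesis lower, and these 3 calls were lost with an estimated correlation (adjusted p = 0.714, 0.648 and 0.648). The p53 target CDKN1A, an inhibitor of the cell cycle, rose from 694 ± 49.3 to 1966 ± 47.1 CPM (edgeR adjusted p = 8.69e-08). MDM2, another p53 target, rose from 268 ± 12.1 to 558 ± 6.75 CPM. MKI67, a marker of cycling cells, fell from 28.6 ± 1.54 to 10.2 ± 1.99 CPM. Among 14185 tested genes, 4403 were higher and 4299 were lower (61.4% called by edgeR), of which 751 and 880 changed at least 2-fold.

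The largest rises with siRNA 1 were in PTPRQ, a receptor-type phosphatase (chromosome 12, 80402178 to 80680271), from 0.386 ± 0.105 to 13.8 ± 1.74 CPM, and SERPINB2, an inhibitor of plasminogen activators (chromosome 18, 63871692 to 63903890), from 0.711 ± 0.158 to 23.3 ± 2.28 CPM. Their log2 fold changes were 5.15 ± 0.178 and 5.03 ± 0.177. ANO3 (4.23), ZC3H12B (3.09), SLIT2, a secreted guidance cue (2.98), the chemokines CXCL8 (2.88) and CXCL1 (2.58), ANXA1, an annexin (2.75), IFIT2, an interferon-induced gene (2.67), and PLSCR4 (2.52) also rose. CXCL1 is close in sequence to other chemokines of its family, so reads could be shared among them. The largest falls were in SMN2 (−5.06), SLC14A1, a urea transporter (−4.13), INSC (−3.46), ADGRG1 (−3.39), CNIH2 (−3.18), ESRRG (−3.04), PDGFB, a growth factor subunit (−3.04), GRIA4 (−3.00), LIPG, a lipase (−2.97), and PTGS2, the inducible cyclooxygenase (−2.97). SMN2 is a near-identical copy of SMN1, and its estimated counts with the PTCHD4 siRNAs were 0 in 4 of 6 libraries, so how reads were divided between the copies is open. With DESeq2, SMN2 had adjusted p = 0.112 with siRNA 1.

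Of 32 tested p53 targets, 28 rose, 1 fell and 3 did not pass with siRNA 1 (28 and 1 when adjusted over the list alone), with a median log2 fold change of 0.64. TNFRSF10B, a death receptor, rose by 1.90, CYFIP2 by 0.95 and PLK3 by 1.32 on the log2 scale. The list was called by camera (adjusted p = 2.66e-14), also with an estimated correlation (adjusted p = 0.00418). Of 38 interferon-stimulated genes 32 rose and 6 did not pass, also when adjusted over the list alone, with a median of 1.05 (camera adjusted p = 5.90e-06). IFIT3 and IFI44 rose by 1.51 and 1.46. The interferon call was lost with an estimated correlation (adjusted p = 0.714).

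Genes of G2 and mitosis fell with siRNA 1 in 29 of 32 cases, and 3 did not pass, with a median of −1.18 (camera adjusted p = 2.86e-07). The log2 fold change was −1.67 for DLGAP5, which acts on the spindle, −1.43 for PRC1, a protein of the spindle midzone, and −1.18 for ANLN, which acts in cytokinesis. Genes of S phase and replication fell in 19 of 30 cases, 3 rose and 8 did not pass, with a median of −0.50 (camera adjusted p = 0.0451). Adjusted over the list alone, 3 rose and 20 fell. RRM2, a subunit of ribonucleotide reductase, changed by −1.40, MCM6, part of the replicative helicase, by −1.11, SLBP by −0.65, and PCNA, the sliding clamp, by 0.40. With an estimated correlation, both calls were lost (adjusted p = 0.648 for G2 and mitosis and 0.714 for S phase). The S phase call was also lost with total counts only (adjusted p = 0.0599), DESeq2 (0.0806), the stricter filter (0.0841) and only the groups compared (0.127). It was lost without control replicate 2 (0.0530) or 3 (0.0543), siRNA 1 replicate 1 (0.0645) or 2 (0.0503), or siRNA 2 replicate 2 (0.0874) or 3 (0.0788).

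Genes of cholesterol synthesis fell with siRNA 1 in 18 of 23 cases, 1 rose and 4 did not pass, with a median of −0.52 (camera adjusted p = 5.90e-06, and adjusted p = 0.648 with an estimated correlation). INSIG1, which holds back the sterol-regulated transcription factors, changed by −2.87, TM7SF2, a sterol reductase, by −1.98 and SC5D, a sterol desaturase, by −1.04. Of 22 contractile and TGF-beta response genes 13 fell, 3 rose and 6 did not pass, with a median of −0.34 (camera adjusted p = 0.0444, and adjusted p = 0.714 with an estimated correlation). ACTA2, smooth muscle actin, changed by −1.24, CALD1, caldesmon, by −0.84, and CTGF by −0.63. Of 43 ribosomal protein genes 34 rose, 3 fell and 6 did not pass, with a median of 0.27 (camera adjusted p = 0.0390, and adjusted p = 0.714 with an estimated correlation); RPL14 changed by 0.40, RPLP2 by 0.37 and RPL10A by −0.32. Of 15 fibroblast markers, 5 of which the matrix list also holds, 10 rose, 1 fell and 4 did not pass, with a median of 0.32 (camera adjusted p = 6.70e-04, and adjusted p = 0.648 with an estimated correlation). DCN, the proteoglycan decorin, rose by 1.39, TWIST1 by 0.77, COL3A1 by 0.73 and COL1A1 by 0.53. Counts adjusted over the list alone were the same for these 4 lists. The contractile call was lost with the stricter filter (adjusted p = 0.0515) and without control replicate 2 (0.0530), siRNA 1 replicate 2 (0.0503) or siRNA 1 replicate 3 (0.0535). The ribosomal call was lost with total counts only (0.0562), the stricter filter (0.0504) and without control replicate 2 (0.0530), siRNA 1 replicate 1 (0.0524) or siRNA 1 replicate 2 (0.0509).

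The other 17 lists were not called by camera with siRNA 1. Of 9 genes of the patched-domain and sterol-sensing-domain family, 5 fell, 1 rose and 3 did not pass (median −0.63, camera adjusted p = 0.0569, 7 and 1 when adjusted over the list alone); PTCH1, the hedgehog receptor, changed by −0.63, SCAP, the sterol sensor, by −0.79 and DISP2 by −2.90. That list was called with RLE size factors (adjusted p = 0.0417), limma-voom (0.0421), no filter (0.0286), a replicate block (0.0362) and only the groups compared (0.0188). It was also called without siRNA 2 replicate 1 (0.0465), 2 (0.0414) or 3 (0.0221). In the hedgehog pathway 8 of 16 genes rose and 3 fell (median 0.10, camera adjusted p = 0.430), with BMP4 at 0.67, GLI2 at 0.65 and FOXF1 at 0.33. Senescence-associated secretory factors rose in 13 and fell in 8 of 30 cases (median 0.36, camera adjusted p = 0.558), with IGFBP3 at 2.31, CCL2, a chemokine, at 2.02, AREG, a growth factor, at −2.61 and PLAT, tissue plasminogen activator, at −2.38. NF-kB targets rose in 11 and fell in 6 of 21 cases (median 0.20), with TNFAIP6 at 1.74 and TRAF1 at 1.03. Pro-apoptotic genes rose in 11 and fell in 8 of 24 cases (median 0.15), with APAF1 at 1.05 and PMAIP1 at −1.76. Anti-apoptotic genes rose in 6 and fell in 4 of 15 cases (median 0.05), with BIRC5 at −1.71 and MCL1 at −0.46.

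Genes of DNA repair and damage signalling rose in 9 and fell in 17 of 39 cases with siRNA 1 (median −0.15), with CHEK1 at −0.86 and CHEK2 at 1.09. Genes of the unfolded protein and integrated stress response rose in 7 and fell in 17 of 29 cases (median −0.27), with DNAJB9 at −0.67 and SLC7A11, a cystine transporter, at 0.67. Collagens and matrix genes rose in 14 and fell in 11 of 30 cases (median 0.06), with COL11A1 at 0.87 and TNC, tenascin C, at −0.94. YAP and TEAD targets rose in 8 and fell in 10 of 22 cases (median −0.13), with NT5E at 1.28 and CYR61 at −0.64. Genes of hypoxia and glycolysis rose in 8 and fell in 12 of 26 cases (median −0.13), with PDK1 at −1.39 and SLC2A3 at 0.91. Genes of the lysosome and autophagy rose in 14 and fell in 12 of 32 cases (median 0.07), with SQSTM1, an autophagy receptor, at 1.08 and NEU1 at −1.21. Genes of the m6A machinery rose in 8 and fell in 5 of 21 cases (median 0.09), with IGF2BP3 at 0.98 and IGF2BP1 at −0.54. Genes of the RNA interference machinery rose in 3 and fell in 6 of 13 cases (median −0.09), with AGO1 at −0.56 and PRKRA at 0.26. Genes of oxidative phosphorylation rose in 15 and fell in 8 of 34 cases (median 0.09), with NDUFB3 at 0.46 and NDUFS1 at −0.41. Of 5 epithelial cell markers 4 fell (median −0.87), with KRT18 at −1.36, KRT19 at −0.87 and KRT8 at −0.52, and with KRT7 falling from 0.749 ± 0.128 to 0.374 ± 0.0822 CPM. The KRT7 call was lost without control replicate 2 (adjusted p = 0.0548) or siRNA 1 replicate 3 (0.0553). Of 5 endothelial and immune cell markers 1 rose, VWF, from 0.415 ± 0.0872 to 0.954 ± 0.223 CPM, and 1 fell, TEK at −0.47 (median 0.14). Adjusted over the list alone, 4 hedgehog genes, 18 DNA repair genes and 13 matrix genes fell and 9 YAP and TEAD targets rose. Apart from the patched-domain list given above, the counts of the other uncalled lists were unchanged. The mean (−0.04 and −0.03) had another sign than the median for anti-apoptotic and lysosome genes, as it did (0.09) for YAP and TEAD targets, and camera pointed down for the endothelial and immune markers.

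With siRNA 2 against control, which asks the same of the siRNA that left less PTCHD4, camera called interferon-stimulated genes higher and contractile genes, YAP and TEAD targets and mitotic genes lower. With an estimated correlation these 4 calls were lost (adjusted p = 0.746, 0.407, 0.130 and 0.746). CXCL8, a chemokine that draws neutrophils (chromosome 4, 73740506 to 73743716), rose from 0.374 ± 0.0959 to 33.2 ± 12.3 CPM, a log2 fold change of 6.47 ± 0.313. ACTA2 fell from 781 ± 78.6 to 86.7 ± 8.91 CPM, a log2 fold change of −3.17 ± 0.0933. CDKN1A rose to 2134 ± 326 CPM (log2 fold change 1.62 ± 0.0946), while MDM2 fell to 156 ± 15.5 CPM (−0.78 ± 0.0651). Among 14185 tested genes, 5199 were higher and 5593 were lower (76.1% called by edgeR), of which 1113 and 2401 changed at least 2-fold.

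IGFBP1, which binds insulin-like growth factors (chromosome 7, 45888357 to 45893668), stood at 301, 252 and 230 estimated counts in the siRNA 2 libraries, against 1, 1 and 2 in controls and 0, 0 and 1 with siRNA 1. Log2 fold changes among the other largest rises with siRNA 2 were 6.33 for CXCL1, 5.73 for IL1B, the cytokine interleukin 1 beta, 5.47 for CYP1B1, a cytochrome P450, 5.19 for KYNU, a kynureninase, 4.94 for the chemokine CXCL10, 4.77 for C11orf96, 4.76 for SLC16A6 and 4.54 for MX1, an antiviral GTPase. MX1 stood at 105 ± 54.1 CPM with siRNA 2, the widest spread relative to its mean among these rises. The largest falls were in SLC7A14 (−5.68), SMN2 (−5.65), HBD, a globin (−5.47), SORL1, a sorting receptor (−5.38), OXTR, the oxytocin receptor (−5.20), B3GALT2 (−4.93), TNFSF4 (−4.85), KCTD16 (−4.82), KRT19 (−4.73) and GFRA1, a receptor of the GDNF family (−4.70). KCTD16 rested on 1 to 4 estimated counts in the siRNA 2 libraries, and with DESeq2 SMN2 had adjusted p = 0.0584.

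Of 38 interferon-stimulated genes 36 rose and 2 did not pass with siRNA 2 (37 when adjusted over the list alone), with a median of 1.56 (camera adjusted p = 1.23e-05). IFIT2 rose by 3.00, IFIT3 by 1.88 and IFI44 by 1.58 on the log2 scale. Genes of G2 and mitosis fell in 31 of 32 cases and 1 rose, with a median of −1.08 (camera adjusted p = 0.00589). DLGAP5 changed by −1.47, PRC1 by −1.27, MKI67 by −1.24 and ANLN by −1.18. Of 22 contractile and TGF-beta response genes 17 fell, 3 rose and 2 did not pass, with a median of −1.26 (camera adjusted p = 2.94e-08). CTGF changed by −1.56 and CALD1 by −1.31. Of 22 YAP and TEAD targets 18 fell (19 when adjusted over the list alone), 3 rose and 1 did not pass, with a median of −0.87 (camera adjusted p = 6.02e-08). NT5E, an ectonucleotidase, changed by −3.56, IGFBP3 by −2.63 and PTPN14 by −1.04, and CYR61 fell from 498 ± 14.4 to 249 ± 9.33 CPM. Of 21 genes of the m6A machinery, which writes, reads or erases this mark on mRNA, 14 rose, 1 fell and 6 did not pass, with a median of 0.38 (camera adjusted p = 0.0129). The writer subunit KIAA1429, for which the annotation gave no coordinates under this symbol, rose by 0.94, IGF2BP3 by 0.57, IGF2BP1 by 0.53 and HNRNPA2B1 by 0.42. All 5 calls were lost with an estimated correlation, where the adjusted p was 0.746 for the interferon, mitosis and m6A lists, 0.407 for the contractile list and 0.130 for YAP and TEAD targets.

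The other 20 lists were not called by camera with siRNA 2. Of 32 p53 targets 10 rose, 13 fell and 9 did not pass (median −0.10, camera adjusted p = 0.277); PLK3 rose by 1.29 and TNFRSF10B by 0.94, while CYFIP2 changed by −4.01. Senescence-associated secretory factors rose in 19 and fell in 8 of 30 cases (median 0.64, camera adjusted p = 0.130), with AREG at 3.44, CCL2 at −2.51 and PLAT at −2.18. That list was called with no filter (0.0482) and without siRNA 2 replicate 1 (0.0199), 2 (0.0492) or 3 (0.0456). NF-kB targets rose in 13 and fell in 5 of 21 cases (median 0.42), with PTGS2 at 4.33, TNFAIP6 at 3.31 and TRAF1 at −1.41; without siRNA 2 replicate 2 the list was called (0.0239). Genes of the lysosome and autophagy rose in 18 and fell in 10 of 32 cases (median 0.34, camera adjusted p = 0.0514), with SQSTM1 at 2.73, MCOLN1, a lysosomal channel, at 1.63, LAMP2 at 1.44 and NEU1 at 1.22. That list was called with RLE size factors (0.0311), DESeq2 (0.0123), no filter (0.0129) and without siRNA 2 replicate 1 (0.0441), 2 (0.0492) or 3 (0.0109).

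Hedgehog pathway genes rose in 6 and fell in 8 of 16 cases with siRNA 2 (median −0.30), with BMP4 at −1.51, GLI2 at −0.82 and FOXF1 at 0.56. Genes of the patched-domain and sterol-sensing-domain family rose in 2 and fell in 5 of 9 cases (median −0.51), with DISP2 at −2.14 and PTCH1 and SCAP each at −0.51. Genes of cholesterol synthesis rose in 6 and fell in 12 of 23 cases (median −0.40), with TM7SF2 at −1.41 and INSIG1 at 0.73. Genes of S phase and replication rose in 11 and fell in 8 of 30 cases (median 0.05), with RRM2 at −1.88, MCM6 at −1.31 and SLBP at 0.97. Pro-apoptotic genes rose in 10 and fell in 9 of 24 cases (median −0.03), with APAF1 at 1.52 and PMAIP1 at −1.40. Anti-apoptotic genes rose in 7 and fell in 7 of 15 cases (median −0.10), with BIRC5 at −1.76 and MCL1 at 0.55. Genes of DNA repair and damage signalling rose in 17 and fell in 12 of 39 cases (median 0.18), with TP53BP1 at 0.85, MSH6 at 0.83 and CHEK1 at −0.99. Genes of the unfolded protein and integrated stress response rose in 13 and fell in 7 of 29 cases (median 0.17), with SLC7A11 at 1.46 and DNAJB9 at −0.83. Collagens and matrix genes rose in 11 and fell in 13 of 30 cases (median −0.08), with COL6A3 at −2.62, TNC at −2.33 and COL3A1 at 0.57. Genes of hypoxia and glycolysis rose in 13 and fell in 8 of 26 cases (median 0.09), with ALDOC at −2.05 and P4HA2 at 0.54.

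Genes of the RNA interference machinery rose in 6 and fell in 3 of 13 cases with siRNA 2 (median 0.09), with AGO1 at −1.18, AGO3 at −0.96 and PRKRA at 0.43. Ribosomal protein genes rose in 5 and fell in 17 of 43 cases (median −0.10), and 11 fell when adjusted over the list alone, with RPL14 at 0.32 and RPL10A at −0.27. Genes of oxidative phosphorylation rose in 14 and fell in 12 of 34 cases (median −0.02), with UQCRFS1 at 0.50 and NDUFB3 at −0.50. Of 5 epithelial cell markers 3 fell (median −1.92), with KRT7 at −2.35 and KRT8 at −1.92. KRT8 and KRT18 overlap in the annotation, and KRT18 had 0.04 (−0.02 with total counts only) and did not pass. Of 5 endothelial and immune cell markers 2 rose (median 0.26), with CD14 at 1.52 and TEK at 0.96. Fibroblast markers rose in 6 and fell in 7 of 15 cases (median 0.01), with TWIST1 at 2.34, COL1A1 at 0.59 and DCN at 0.41. Counts adjusted over the list alone were the same for the lists where none is given. The sign of the mean differed from that of the median for S phase (−0.06), pro-apoptotic (0.05), DNA repair (−0.01), hypoxia (−0.06) and fibroblast (−0.18) genes. Camera pointed up for pro-apoptotic, anti-apoptotic and oxidative phosphorylation genes, whose medians were negative, and down for hypoxia genes and fibroblast markers, whose medians were positive.

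**Figure D2:**
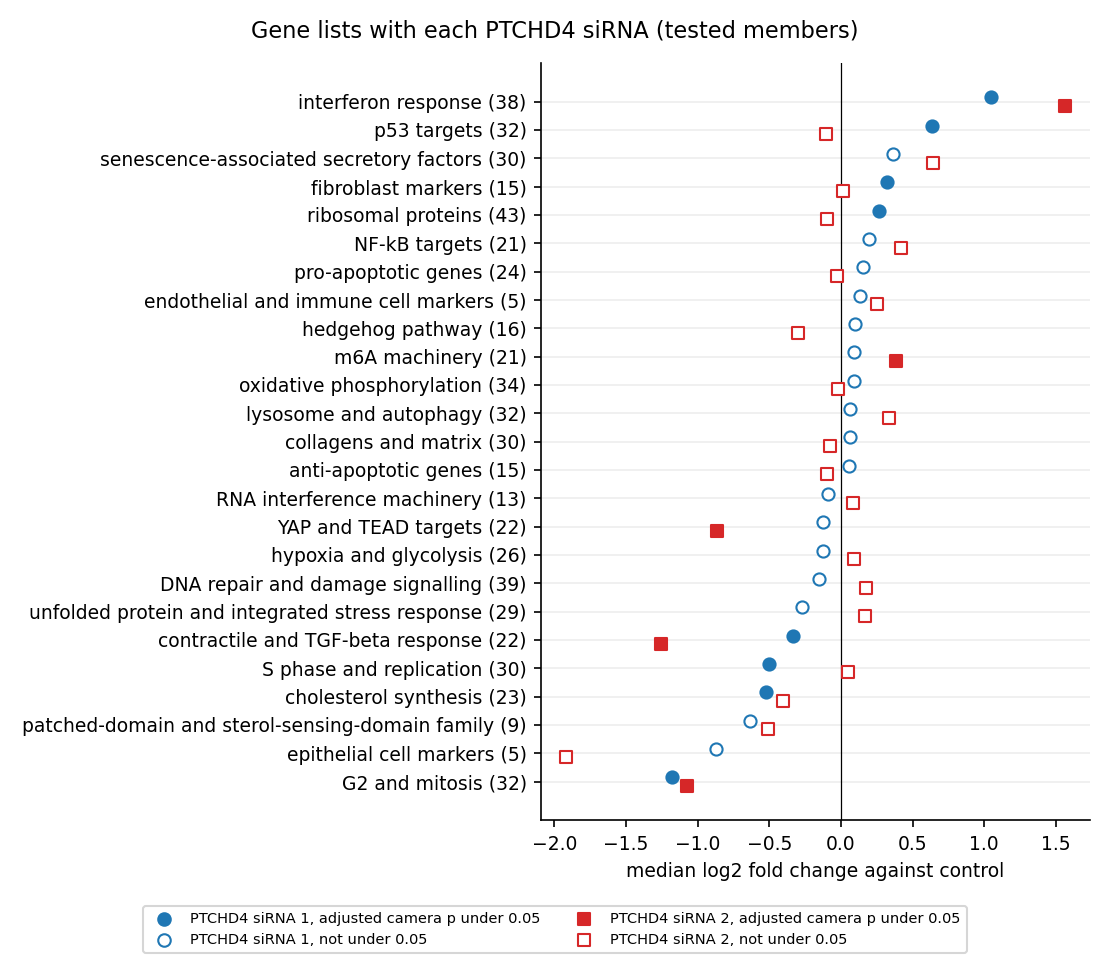
Median log2 fold change against control of the tested members of each of 25 gene lists, with circles for siRNA 1 and squares for siRNA 2, filled where the adjusted camera p was under 0.05. Interferon-stimulated genes lie to the right with both siRNAs (1.05 and 1.56), and p53 targets with siRNA 1 (0.64) but not with siRNA 2 (−0.10).

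Set directly against each other, the siRNAs differed in p53 targets as a list (camera adjusted p = 0.0151 with an estimated correlation). Among single genes, PTGS2 was at 1.05 ± 0.106 CPM with siRNA 1 and 166 ± 34.5 CPM with siRNA 2, with 8.23 ± 1.11 CPM in controls. AREG was at 2.84 ± 0.0633 and 189 ± 19.8 CPM, with 17.4 ± 0.719 CPM in controls. IGFBP3 went the other way, with 541 ± 54.9 CPM with siRNA 1, 17.6 ± 0.778 CPM with siRNA 2 and 109 ± 7.50 CPM in controls. Of 14185 tested genes, 5214 were higher and 5597 lower with siRNA 2 than with siRNA 1 (76.2% called by edgeR), and 1289 and 2393 differed at least 2-fold.

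The largest log2 differences (siRNA 2 minus siRNA 1) were 7.30 for PTGS2, 6.91 for IL1B, 6.54 for C11orf96 and 6.06 for AREG, beside IGFBP1, whose counts are given above, and −6.72 for KCTD16, −6.16 for GSG1, −5.78 for PTPRQ, −5.27 for GFRA1 and −5.10 for ABCA12, a lipid transporter. Of 32 p53 targets 26 were lower with siRNA 2, 3 higher and 3 did not pass, with a median of −0.91 (camera adjusted p = 4.33e-09, and adjusted p = 0.0151 with an estimated correlation). CDKN1A differed by 0.12 (edgeR adjusted p = 0.263) and MDM2 by −1.83 (edgeR adjusted p = 2.20e-10). Camera called 8 further lists, all lost with an estimated correlation. YAP and TEAD targets were lower with siRNA 2 in 18 and higher in 3 of 22 cases (median −0.60, camera adjusted p = 3.14e-08, and adjusted p = 0.0631 with an estimated correlation). Contractile and TGF-beta response genes were lower in 17 and higher in 4 of 22 cases (median −0.82, camera adjusted p = 5.45e-05, and adjusted p = 0.567 with an estimated correlation). Fibroblast markers were lower in 12 and higher in 1 of 15 cases (median −0.62, camera adjusted p = 0.00519, and adjusted p = 0.567 with an estimated correlation). Genes of the unfolded protein and integrated stress response were higher in 20 and lower in 6 of 29 cases (median 0.49, camera adjusted p = 0.0219, and adjusted p = 0.567 with an estimated correlation).

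Genes of the m6A machinery were higher with siRNA 2 than with siRNA 1 in 13 and lower in 5 of 21 cases (median 0.38), and genes of the lysosome and autophagy higher in 18 and lower in 10 of 32 cases (median 0.38). Ribosomal protein genes were lower in 34 and higher in 1 of 43 cases (median −0.33). Each of these 3 lists had a camera adjusted p = 0.0379, and adjusted p = 0.567, 0.567 and 0.715 with an estimated correlation. Collagens and matrix genes were lower in 14 and higher in 7 of 30 cases (median −0.10, camera adjusted p = 0.0444, and adjusted p = 0.715 with an estimated correlation). Adjusted over the list alone, the counts of these 9 lists were the same. The collagen, lysosome and m6A calls were lost with limma-voom (adjusted p = 0.213, 0.0998 and 0.0607) and with the stricter filter (0.0523, 0.0523 and 0.0577). These calls and the ribosomal call were lost without siRNA 1 replicate 2 (0.0503 each), the collagen and ribosomal calls without siRNA 2 replicate 1 (0.0535 and 0.0512), and the collagen call without siRNA 2 replicate 3 (0.0554).

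The other 16 lists were not called by camera between the siRNAs. Interferon-stimulated genes were higher with siRNA 2 in 18 and lower in 7 of 38 cases (17 and 6 when adjusted over the list alone), with a median of 0.37 (camera adjusted p = 0.211). Genes of G2 and mitosis were higher in 5 and lower in 6 of 32 cases (5 and 3 when adjusted over the list alone), with a median of −0.01 and a mean of 0.01 (camera adjusted p = 0.787). Genes of cholesterol synthesis were higher in 13 and lower in 8 of 23 cases (median 0.32, camera adjusted p = 0.0983), and that list was called with no filter (0.0472), a replicate block (0.0350) and without siRNA 2 replicate 3 (0.0383). Genes of S phase and replication were higher in 17 and lower in 7 of 30 cases (18 and 7 when adjusted over the list alone; median 0.50, camera adjusted p = 0.125), and that list was called with no filter (0.0472). Hedgehog and pro-apoptotic genes had medians of 0.02 and 0.07 and means of −0.45 and −0.02, and camera pointed up for anti-apoptotic genes, whose median was −0.05.

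On what both siRNAs had in common, camera called interferon-stimulated genes higher and mitotic genes lower with each. With an estimated correlation these list calls were lost (adjusted p = 0.714 and 0.648 with siRNA 1, and adjusted p = 0.746 for each list with siRNA 2). Of the genes called with both, 2120 were higher with both and 2260 were lower with both, against 1613.8 and 1695.1 if the calls were independent. In opposite directions, 1343 were higher with siRNA 1 and lower with siRNA 2 and 1209 the reverse, against 1736.1 and 1575.6 if independent, so fewer than independent calls give. Both sets of calls use the same control libraries, so they are not independent by design. An effect of the control siRNA would also add calls the same way, so the excess alone does not show a shared response to the PTCHD4 siRNAs. Thus 63.2% of the 6932 genes called with both moved the same way. At least 2-fold changes the same way numbered 197 higher and 405 lower. Of the 4380 genes called the same way, 2904 also differed between the siRNAs.

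The genes that rose most with both siRNAs included CXCL8, CXCL1, IFIT2, SERPINB2 and ZC3H12B. OAS2, an antiviral synthetase, rose by 2.35 with siRNA 1 and 3.11 with siRNA 2 on the log2 scale, TNXB by 2.13 and 2.22, IFI6, an interferon-induced gene, by 2.09 and 2.25, ZNF559 by 1.87 and 1.88, and NEAT1, a long non-coding RNA, by 1.86 and 2.25. CEMIP, which breaks down hyaluronan, fell from 734 ± 84.7 CPM in controls to 106 ± 3.39 and 57.9 ± 4.66 CPM. PLAT fell from 887 ± 28.5 CPM to 170 ± 2.83 and 196 ± 12.8 CPM. TMEM154 changed by −2.91 and −3.57 on the log2 scale, LDB2 by −2.32 and −3.41, and CDH4, a cadherin, by −2.22 and −4.56. With siRNA 2, ESRRG changed by −3.97, PDGFB by −2.41 and SLC14A1 by −2.36.

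**Figure D3:**
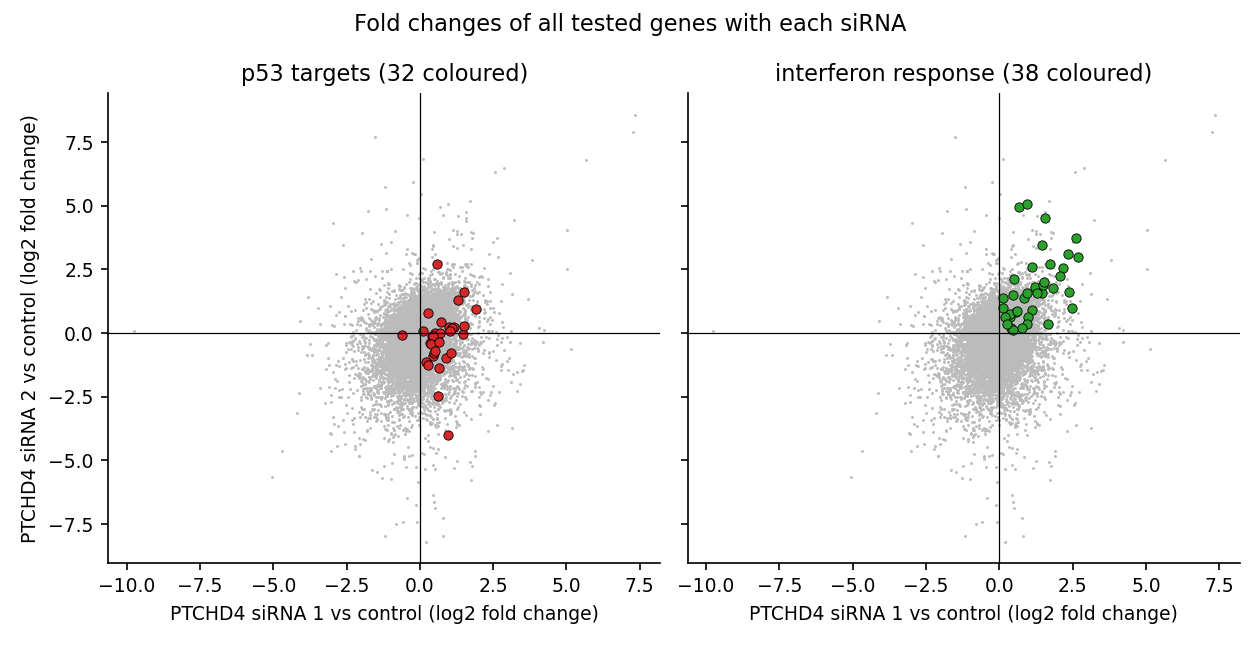
Log2 fold change against control of every tested gene with siRNA 1 (x axis) and siRNA 2 (y axis), with 32 p53 targets coloured in the left panel and 38 interferon-stimulated genes in the right. The interferon-stimulated genes lie up and to the right, and the p53 targets spread along the vertical axis.

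Across genes, which are not independent replicates, the log2 fold changes of the siRNAs had a Pearson correlation of 0.233 and a Spearman correlation of 0.232. Simulated libraries without any change, tested against shared controls, gave a median correlation of 0.482 over 20 draws. Their fold changes hold noise only, so this value is no limit to set the observed correlation against. The covariance was 0.174 against a simulated 0.0114, so noise between the shared control libraries gave a small part of it. A difference common to all control libraries was not simulated. It would enter both comparisons, and its part in the covariance is not known. The simulated draws gave 0 genes called the same way, but they called at most 1 gene in a comparison. They cannot show what shared controls add where many genes change. The same sign was seen in 58.1% of tested genes, against a simulated 66.4% that likewise comes from noise only.

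Among genes fixed for their roles in the cell cycle, hedgehog signalling, apoptosis and senescence, PTCH1 fell from 46.4 ± 1.12 CPM to 29.9 ± 1.14 with siRNA 1 and 32.5 ± 2.26 with siRNA 2. GLI1, a hedgehog target and transcription factor, was at 0.541 ± 0.123 CPM in controls and had log2 fold changes of −0.47 and −0.46, which did not pass (edgeR adjusted p = 0.194 and 0.179). LMNB1, a lamin that is low in senescent cells, had −0.15 and −0.16 and did not pass (edgeR adjusted p = 0.311 and 0.246). The anti-apoptotic BCL2 rose from 2.38 ± 0.246 CPM to 3.17 ± 0.562 and 3.43 ± 0.515 CPM. The siRNA 1 call of BCL2 (edgeR adjusted p = 0.0388) was lost with total counts only (0.0606) and without control replicate 1 (0.0744), control replicate 2 (0.125) or siRNA 1 replicate 3 (0.187). BCL2L1, also anti-apoptotic, fell by 0.52 with siRNA 2 and had 0.04 with siRNA 1, which did not pass. IL6, a secreted cytokine, fell from 6.04 ± 0.554 to 2.81 ± 0.302 CPM with siRNA 1 and was at 5.65 ± 2.20 CPM with siRNA 2, which did not pass (edgeR adjusted p = 0.735).

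**Figure D4:**
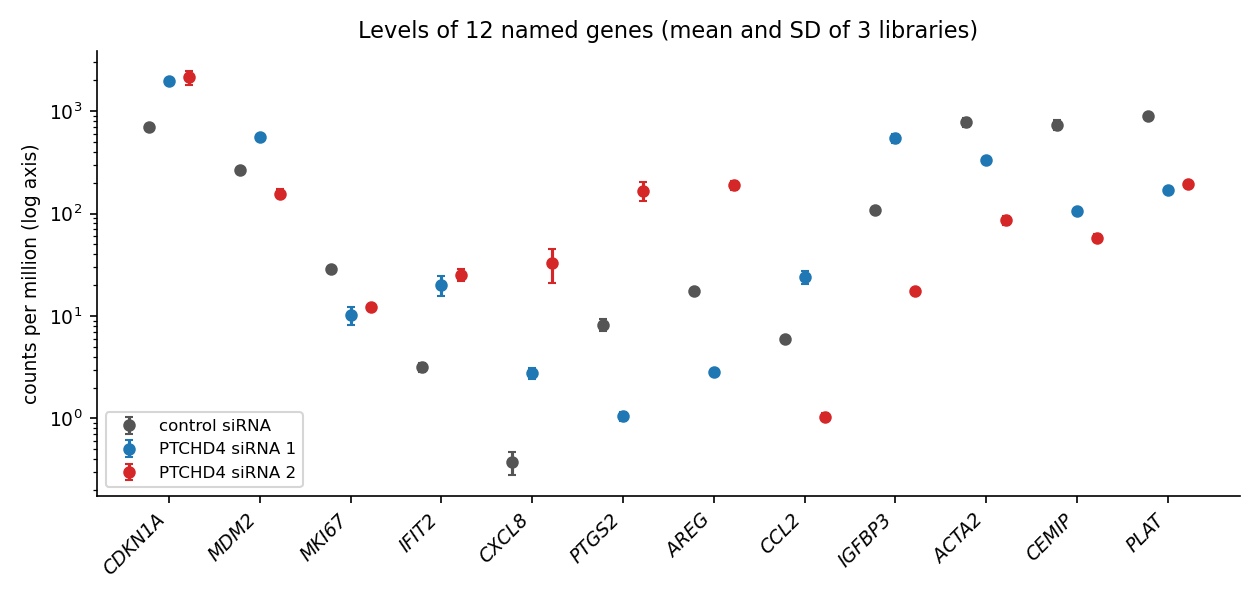
Mean and SD of 3 libraries in CPM on a log axis for 12 genes with control siRNA, siRNA 1 and siRNA 2. CDKN1A was higher and MKI67, CEMIP and PLAT lower with both siRNAs, while PTGS2, AREG, CCL2 and IGFBP3 moved in opposite directions.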

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

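The tests of 7-mers, of unequal silencing, of the extent of silencing for p53 targets and of duplex sensing were chosen only after the results they address were seen.

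The siRNAs moved many genes apart: of the 6932 genes called with both, 63.2% moved the same way (95% binomial interval 62.0 to 64.3%), which argues against unequal silencing of PTCHD4 as the whole cause, under which at least 95% were predicted to move the same way. The 3′ UTR 7-mer most linked to a fall was GGCGTTC with siRNA 1 (z = −9.76, 206 genes) and GCCAACT with siRNA 2 (z = −16.3, 873 genes), and each had little link with the other siRNA (z = −0.36 and −1.22). Each occurs once in exon 3 of the 2850-base PTCHD4 transcript of the annotation (chromosome 6, 47878746 to 47878752 and 47879657 to 47879663 on GRCh38), a transcript that holds 15.4% of all tested 7-mers, and CTCAATT, the next with siRNA 1 (z = −7.87), has its reverse complement placed so that both fit 1 duplex of 19 bases. Seed-matched binding of each siRNA to other transcripts may therefore contribute, but direct repression of this kind is argued against as the whole cause. In 1547 genes the whole transcript, not only the 3′ UTR, holds no 6-mer part of GGCGTTC, CTCAATT or GCCAACT. Of these, 71.4% were called between the siRNAs (95% binomial interval 69.0 to 73.6%), against 76.2% of all tested genes. Among genes named for falling with both siRNAs, TMEM154 has 3 sites of CTCAATT and 1 of GCCAACT in its 3′ UTR. LDB2, CDH4 and SLC14A1 have 1 site of CTCAATT each and CEMIP 1 of GCCAACT, while PLAT, ESRRG, PDGFB and SMN2 have none. Other genes named for falls hold sites too. With siRNA 1, CTCAATT lies in INSIG1, DISP2, CALD1, CTGF, CYR61 and AGO1. With siRNA 2, GCCAACT lies in NT5E, COL6A3, SORL1, GLI2, AGO3 and BIRC5. Such falls may be direct, but a site alone does not show it. DCN, MDM2 and ZNF559 hold CTCAATT and rose with siRNA 1, and KYNU and SLC7A11 hold GCCAACT and rose with siRNA 2. Indirect effects of the seed targets and true effects of lower PTCHD4 stay open. The siRNA sequences that would settle the seeds are not given in the sources used here.

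The p53 targets rose with siRNA 1, which left 75.2% of PTCHD4, and were lower with siRNA 2 than with siRNA 1 (median −0.91, camera adjusted p = 0.0151 with an estimated correlation), which argues against an effect that follows the extent of silencing. CDKN1A, a p53 target, rose by 1.62 on the log2 scale with siRNA 2 too. Whether the rise with siRNA 1 comes from lower PTCHD4 or from other transcripts stays open.

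Interferon-stimulated genes were called higher by camera with both siRNAs, calls lost with an estimated correlation (adjusted p = 0.714 and 0.746). A 7-mer, AGCCTTA, was the most linked to a rise with each, and a seed effect of the control siRNA through it could lower such genes in the controls. Over the 32 members without that 7-mer in the 3′ UTR, the median was 1.05 with siRNA 1 (95% bootstrap interval 0.72 to 1.51) and 1.56 with siRNA 2 (0.93 to 1.88). This argues against 3′ UTR sites of this exact 7-mer in these genes as the cause. Members with overlapping 7-mers such as TAGCCTT (z = 8.07 with siRNA 1 and 6.80 with siRNA 2) were not left out, so related sites stay open. The intervals draw members, which move together (estimated correlation 0.701 and 0.722 over the list). They do not measure the spread between libraries. Sensing of the siRNA duplexes and loss of PTCHD4 cannot be told apart for this list, since its difference between the siRNAs (median 0.37, camera adjusted p = 0.211) does not go against the order of silencing. The series holds no library without siRNA, which could help to separate them.

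PTCHD4 itself differed between the siRNAs by −1.63 on the log2 scale. Further lists differed between the siRNAs by camera, with medians (siRNA 2 minus siRNA 1) of 0.49 for the unfolded protein and integrated stress response, −0.10 for collagens and matrix, −0.82 for contractile and TGF-beta response genes, −0.60 for YAP and TEAD targets, 0.38 for lysosome and autophagy, 0.38 for the m6A machinery, −0.33 for ribosomal proteins and −0.62 for fibroblast markers. All 8 calls were lost with an estimated correlation (adjusted p = 0.0631 for YAP and TEAD targets and 0.567 to 0.715 for the others). Some named genes changed at least 2-fold in opposite directions with the siRNAs, each by a called difference. Their log2 differences were −5.10 for ABCA12, 6.06 for AREG, 6.54 for C11orf96, −4.53 for CCL2, −6.16 for GSG1, −4.95 for IGFBP3, −6.72 for KCTD16, 2.42 for NEU1, −4.84 for NT5E, 7.30 for PTGS2 and −2.44 for TRAF1.

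Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. The real split called 8702, 10792 and 10811 genes for siRNA 1, siRNA 2 and siRNA 2 against siRNA 1, and the highest other split called 0 in each, so 1 of 10 gave as many. For lists, the real splits called 8, 5 and 9 and the highest other splits 8, 8 and 9, so 2, 5 and 3 of 10 gave as many. For genes changed the same way with both siRNAs, 2 of 100 drawn splits, the real one included, gave as many as the real 4380. This sets the groups apart from most random groupings of the libraries but does not test whether the PTCHD4 siRNAs agree. The highest other split, 6633, put the siRNA 2 trio in the place of the controls and mixed control and siRNA 1 libraries in the other groups. A count this high thus did not need the real groups, which points to a structure of the samples.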

How the results depend on the processing

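All alternatives were planned. PTCHD4, the gene counts and the correlation of fold changes kept their direction, and the gene counts stayed within 1.5 times, except under a 2-fold minimum. That minimum left 751 higher and 880 lower genes with siRNA 1, 1113 and 2401 with siRNA 2, 1289 and 2393 between the siRNAs, and 197 higher, 405 lower and 202 opposite with both, because it takes a part of the called genes. The number of lists called was 5 with siRNA 1 under the stricter filter. With an estimated correlation it was 1, 0 and 1 for siRNA 1, siRNA 2 and siRNA 2 against siRNA 1, and with fry, which asks another question, 17, 20 and 22.

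Leaving out 1 library gave 3929 to 4762 higher and 3854 to 4813 lower genes with siRNA 1, 4907 to 5358 and 5265 to 5599 with siRNA 2, and 4932 to 5454 and 5323 to 5627 between the siRNAs. Both higher ran from 1862 to 2311, both lower from 2017 to 2491, opposite from 2151 to 2801 and the correlation from 0.210 to 0.257. PTCHD4 ran from −0.48 to −0.33, from −2.10 to −1.95 and from −1.69 to −1.55. Lists called ran from 5 to 9, 5 to 8 and 5 to 9; 5 with siRNA 1 came without control replicate 2 or siRNA 1 replicate 2, 8 with siRNA 2 without siRNA 2 replicate 2, and 5 between the siRNAs without siRNA 1 replicate 2. The cause of these moves in list number was not tested.

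Some lists that were not called turned direction, with these adjusted p values and, in brackets, the range with 1 library left out where such a setting turned it too. With siRNA 1 these were anti-apoptotic genes (fry 0.956 [0.929 to 0.993]), YAP and TEAD targets (limma-voom 0.914), lysosome and autophagy (limma-voom 0.843, only the groups compared 0.944 [0.829 to 0.958]), and endothelial and immune markers (RLE 1.00, limma-voom 0.917, no filter 0.923). With siRNA 2 they were hypoxia (RLE 0.991, limma-voom 0.648 [0.793 to 0.973]) and oxidative phosphorylation (fry 0.460 [0.793 to 0.977]). Between the siRNAs it was oxidative phosphorylation (RLE 0.932, DESeq2 0.832, no filter 0.927 [0.874 to 0.999]). Uncalled genes that turned were KRT18 with siRNA 2 (log2 fold change −0.018 with total counts only [−0.045 to 0.12]), CD14 with siRNA 1 [−0.011 to 0.23] and IL6 with siRNA 2 [−0.40 to 0.16]. The cause was not tested.

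Of values for named genes, 2422 of 2430 with a library left out and 2418 of 2422 under other settings kept direction and side of the threshold. For lists these were 638 of 675 and 730 of 825. With replicate number as a block, 4557 and 4460 genes were called with siRNA 1, 5274 and 5712 with siRNA 2, and PTCHD4 was −0.41 and −2.03. A general pairing by number was not seen: correlations of residuals between libraries of the same number ran from −0.0683 to 0.243. Of 9 libraries, 3 correlated best with their own number. With 3 libraries in a group, this check cannot exclude a pairing. Depth limits genes near the floor, such as IGFBP1, KCTD16, DISP2 and KRT7.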

Other observations

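The tests of AGCCTTA and of NRF2 targets were chosen only after the results they address were seen.

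NQO1, a quinone reductase, rose from 466 to 853 CPM with siRNA 1 and 1128 CPM with siRNA 2, TXNRD1, a thioredoxin reductase, from 746 to 1248 and 2127 CPM, and GCLM, which acts in glutathione synthesis, from 40.5 to 62.4 and 125 CPM. HMOX1, heme oxygenase, rose from 17.0 to 23.3 and 186 CPM, and AKR1C1, an aldo-keto reductase, from 27.0 to 96.0 and 417 CPM. These genes were chosen after their values were seen. Of 23 targets of NRF2, a transcription factor of the oxidative stress response, 21 rose, 1 fell and 1 did not pass with each siRNA (median 0.59 with siRNA 1 and 1.00 with siRNA 2, adjusted p = 0.40 and 0.186 with an estimated correlation).

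The list of NRF2 targets was written after HMOX1, AKR1C1, AKR1C2 and SLC7A11 had been noticed, and the test was narrowed to the 19 other members and adjusted as a 26th list only after a first result over all 23 was known. That first result, camera with an estimated correlation and unadjusted, was p = 0.0307 with siRNA 1 and p = 0.0143 with siRNA 2. Adjusted as a 26th list, these were 0.40 and 0.186. Over the 19 other members, 17 rose with each siRNA (medians 0.52 and 0.89), and camera of limma with an estimated correlation gave an unadjusted p = 0.0414 and p = 0.0330 and an adjusted p = 0.538 and p = 0.286. With the preset correlation of the other lists, the adjusted p over the 19 was 5.63e-06 with siRNA 1 and 8e-07 with siRNA 2. Whether the list rises as a set beyond other genes is thus undecided. A siRNA 2 seed site in KEAP1, which restrains NRF2, was tested as a hypothesis and argued against: its 3′ UTR has 0 sites, and KEAP1 had a log2 fold change of 0.17 with siRNA 2 (edgeR adjusted p = 0.0709).

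The 7-mer AGCCTTA was the most linked to a rise with siRNA 1 (z = 8.35) and with siRNA 2 (z = 7.02), and 1283 genes hold it in the 3′ UTR. Of the genes that hold it, 26.6% were called higher with both siRNAs, against 14.3% of those without it. The 7-mer was picked from these same fold changes, so these shares are no separate test. Whether a seed effect of the control siRNA raises such genes in both comparisons, which share the controls, was left open. Neither AGCCTTA nor its reverse complement occurs in the annotated PTCHD4 transcripts of 2850 and 3232 bases.

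The 3232-base PTCHD4 transcript holds neither GGCGTTC nor GCCAACT, while the 2850-base transcript holds each of them. The files give 1 value for the gene, so levels of the transcripts cannot be compared.

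Fewer genes were detected with siRNA 2. Thinned to the smallest total, siRNA 2 libraries had 15842, 16064 and 16371 genes with any count and the other libraries 16635 to 16848, which argues against lower depth as the cause.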
